A study of Acipenser schrenckii with 2 samples.

How the data were processed

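Scanner values and a table of processed values were used for the 2 arrays, which carried gonad RNA of 1 female and 1 male Amur sturgeon of 11 months, grouped by the sex given in the labels. Per the series' design text, 4 to 8 µg of total RNA of each fish entered the assay, and the labelling protocol in the labels gives a lower range. Per the labels, small RNAs were isolated with a size filter, extended with a poly(A) tail and ligated to a tag for Cy3 staining. The scanner files give, per the file headers, the median Cy3 intensity and the pixel SD of each of 3968 spots. Of these spots 3315 belonged to 663 miRNA probes and 653 were controls, of which 361 were empty. The values are not corrected for background, since empty spots had medians of 86.7 and 80.5, and the array software is not given in the sources used here.

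The authors' deposited value table holds 1 linear intensity per probe, with a median of 138 for the female and 150 for the male array. Set against the scanner values of the same array it correlated across probes with r = 0.995 and 0.993 (rho = 0.983 and 0.986), so its scale is linear and its direction clear. Its lowest value of 0.01 was shared by 17 female and 10 male probes, as after background subtraction with a floor. Its ratio to the background-subtracted scanner value changed with brightness, from 1.29 to 1.04 in the female and from 0.684 to 0.935 in the male, so the arrays had been set level by a factor that depends on intensity. The method, and the centring it gives, stay unknown, and the table served as an alternative.

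In R 4.3.3 with limma 3.58.1, scanner values were background corrected by normexp with offset 50 over all spots, averaged on the log2 scale over the 5 spots of a probe, and quantile normalized between the arrays over the 663 miRNA probes. Digit separators in the files were removed on reading. A probe was detected where at least 3 of 5 spots exceeded the 95th percentile of the array's empty spots (103 female, 113 male), since the files give no background SD. Where a probe was detected on 1 array only, the fold is a lower bound against the higher of its own value and the lowest detected value of the other array. The median SD over the spots of a detected probe was 0.11 on either array. The number of arrays, 1 per sex, limits the precision. Quantile normalization gives both arrays 1 distribution, so a global difference between the sexes cannot be seen, and it favours a balanced split of higher and lower probes.

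The size rule, the alternatives, the rule for named probes and 29 miRNA lists were fixed before the data were examined. Lists comprised 17 families and 12 sets of markers of cell types that the dissected tissue could hold. A list's shift is the median difference of its detected names, the brightest probe standing for each name. It was placed among 10000 random lists of the same size, each member drawn from 40 brightness neighbours, as a description of these arrays (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A list of 1 name is thus placed among 40 values only, so its percentile is coarse. Named were up to 12 probes per side with the largest difference and an intensity of at least 500 in the brighter array, miR-202, up to 4 members per list past the rule or else the brightest member, and the 5 brightest probes of each array. Names and targets are those of the chip design; no sturgeon genome was used here, so no position is given.

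The rule was tested on simulated data: in 20 simulated pairs of arrays made from the means and spot SDs of the 663 probes, it recovered 37.9% of 383 probes changed by 1, 86.9% of 390 changed by 1.5 and 93.8% of 389 changed by 2 on the log2 scale, and called 0.148% of unchanged probes. The list step placed 10 of 10 lists of 12 names shifted by 0.6 beyond the central 95% and 0 of 10 unshifted lists. These simulations hold spot error only, drawn as normal noise with each probe's spot SD, and probe changes split evenly up and down. They hold no variation between fish or between hybridisations. Nor do they hold single spots far from the others of their probe, on which 6 of the 31 calls in the data rested. The rate for unchanged probes is thus not the error rate of these arrays.

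Alternatives were 75th percentile scaling (2 kinds), cyclic loess, no normalization, plain subtraction of the empty-spot median, no background correction, offset 16, the median of spots, leaving out each repeat spot, the authors' table (log2 with 50 added; it has no repeat spots), other size, detection and overlap limits, and other ways to treat list members. Added after seeing the data were scaling to the P control probes, leaving out spots over 0.5 from their probe's median, and reducing near-identical targets to the brightest probe. Control spots stayed out of the comparison.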

Results

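The series holds 2 single-colour miRNA arrays of Amur sturgeon (Acipenser schrenckii), a large freshwater fish of the Amur basin. One array carried RNA of a female gonad and the other RNA of a male gonad, each from 1 fish of 11 months, an age that the labels place early in sex differentiation. The title of the series puts the question as one of miRNA expression that differs between the sexes. MicroRNAs (miRNAs) are short RNAs that lower the output of target mRNAs, and the chip reads each through a complementary probe spotted 5 times. Of its 663 probes, 615 were built for miRNAs of other fishes (254 zebrafish, 115 medaka, 110 channel catfish, 81 common carp and fewer of other species, by name prefix), and 48 were custom sequences. The prefixes dre, ola, ipu, ccr, hhi and pol below are those of the probe design, and a probe is not evidence that the sturgeon holds exactly that sequence.

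Both gonads gave signal on most of the chip. The female array had 476 detected probes (71.8%) and the male array 430 (64.9%), with 416 detected on both, 60 on the female array only and 14 on the male array only. Probes detected only on the female array were dim, with a median background-subtracted intensity of 22.6 and a maximum of 60.7. The detection limit lay nearer the empty-spot median on the female array (103 against 86.7) than on the male array (113 against 80.5). The counts of the arrays are thus not at an equal limit. The summed intensity of miRNA spots was 5.53e+06 on the female and 7.03e+06 on the male array, and the median of empty spots was 86.7 and 80.5. The 5 brightest probes of either sex were drawn from pol-miR-133-5p (15.61 on the log2 scale in both), the miR-21 probes dre-miR-21, ola-miR-21 and pol-miR-21-5p (14.65 to 14.67), and the miR-145 probes ipu-miR-145 and dre-miR-145 (14.45 to 14.51). miR-133 is known from striated muscle, miR-21 from many tissues and miR-145 from smooth muscle and mesenchyme. The other 10 detected miR-133 probes, of either arm, were far dimmer (6.89 to 10.34), so the value of pol-miR-133-5p rests on that probe alone. Its equal value on both arrays follows from its top rank under quantile normalization and was not measured. Before normalization it read 55324.5 in the female and 46962.8 in the male, while the authors' table has 50409.1 and 56178.4.

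Male against female gonad was the comparison that the design implies. The male gonad gave more signal for miR-34b and miR-34c, miRNAs known from male germ cells and multiciliated cells. The difference was 3.32-fold and 4.91-fold for the miR-34b probes ipu-miR-34b and dre-miR-34b, which have almost the same target. For miR-34c it rests on a single dim probe, dre-miR-34c, not detected on the female array. That probe read 220 on the male array, background subtracted and before normalization. The female gonad gave more for miR-192 and miR-194, known from kidney and gut epithelium, by 2.02-fold to 2.47-fold for 4 probes. Across the chip, 23 probes were higher in the male gonad, 8 were higher in the female gonad and 459 of the 490 detected on at least one array were neither. Levels on the arrays correlated with r = 0.968 across the 416 probes detected on both, which are not independent replicates. Probes differ widely in brightness on either array, so this does not show how much of the profile the sexes share.

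With 1 animal and 1 array per sex, no test between the sexes was possible, no p-value is given, and the ± values below are SDs over 5 repeat spots on a chip, which are technical. A probe counted as higher where it was detected in the brighter array, differed by at least 1 on the log2 scale and had no overlap between its spots on the arrays. The split rests on the scaling: before normalization the male array was brighter by a median of 0.45 on the log2 scale (1.36-fold), and all differences here are relative to that shift. Cyclic loess gave 30 male-higher and 4 female-higher probes, no normalization 74 and 0, and scaling to the chip's P control probes 105 and 0. Plain background subtraction gave 38 and 33, and a smaller offset of 16 in the background correction 27 and 15, so the count in each direction depends on how the arrays are set level and on the background step. The offset of 50 used here also shrinks the differences of dim probes: with offset 16, ipu-miR-202 differed by 2.36 on the log2 scale, against 1.90 here. In the authors' table, dre-miR-34b was 9.65-fold and ipu-miR-202 14.6-fold higher in the male, against 4.91-fold and 3.74-fold here. That table also differs in background step and normalization, so this gap is not the offset's alone.

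**Figure D1:**
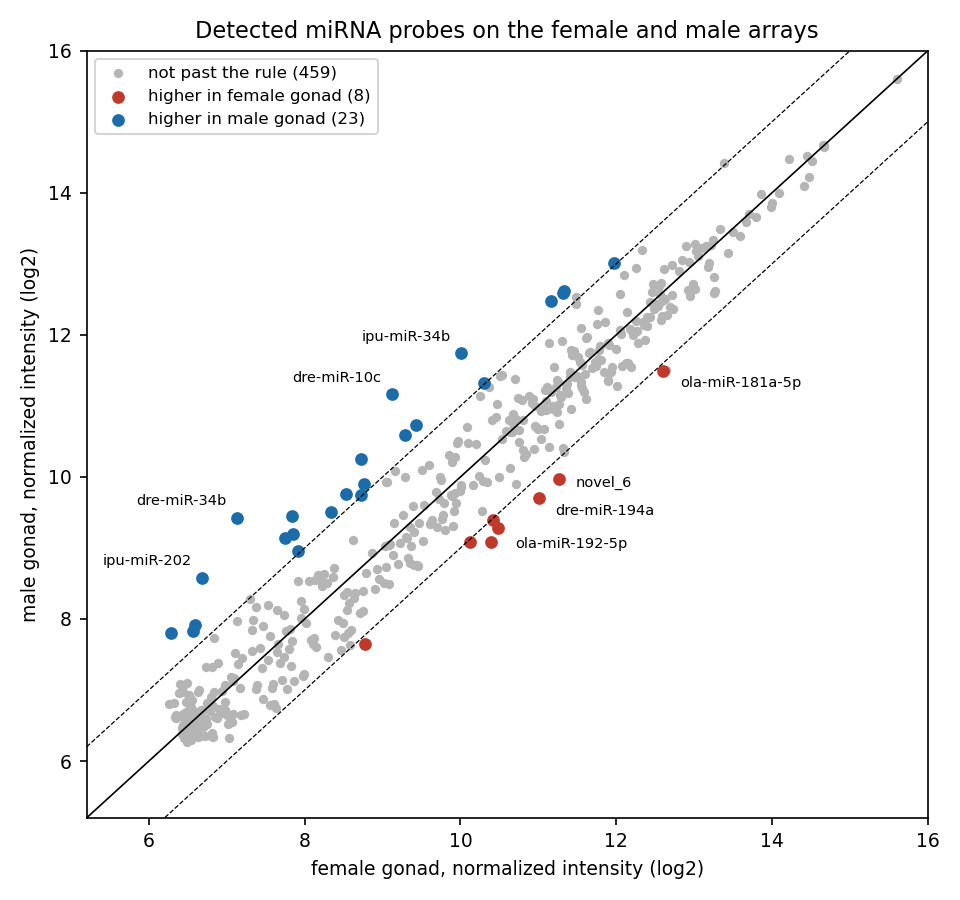
Normalized log2 intensity of the 490 probes detected on at least one array, female gonad on the x axis and male gonad on the y axis, each point the mean of 5 spots. The solid line marks equal values and the dashed lines a difference of 1; 23 blue points were higher in the male gonad and 8 red points higher in the female gonad.

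Of the miR-34 and miR-449 list, 5 probes were detected and 3 were higher in the male gonad. ipu-miR-34b (target AGGCAGUGUUGUUAGCUGAUUGU) read 10.005 ± 0.15 in the female and 11.74 ± 0.07 in the male gonad, and dre-miR-34b 7.13 ± 0.11 and 9.43 ± 0.16. The targets of these miR-34b probes are the same sequence shifted by a single base, so the probes are not independent. dre-miR-34c was not detected on the female array and was at least 2.61-fold higher in the male. hhi-miR-449 differed by 0.88 and dre-miR-34a by -0.27, and neither passed. The list's median difference of 1.20 lay above 99.97% of 10000 random lists matched on brightness.

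miR-202, a miRNA enriched in vertebrate gonads, gave conflicting readings. ipu-miR-202 (UUCCUAUGCAUAUACCUCUUU) read 6.68 ± 0.12 in the female and 8.58 ± 0.31 in the male gonad, 3.74-fold higher in the male. dre-miR-202-5p (UUCCUAUGCAUAUACCUCUUUG), whose target holds the same sequence with 1 more base, was detected on neither array, with 6.25 ± 0.16 and 6.38 ± 0.23, and dre-miR-202-3p was not detected either. The list's median of 1.90 therefore rests on 1 probe and is 0.12 when undetected members count. As a list of 1 name it was compared with its 40 brightness neighbours only, and lay above them.

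Among 19 detected probes of the miR-10, miR-99, miR-100 and miR-125 list, whose miR-10 members lie within Hox gene clusters, 3 were higher in the male gonad and none in the female. dre-miR-10c read 9.12 ± 0.51 and 11.17 ± 0.13 in female and male, ccr-miR-10d differed by 1.02, and ola-miR-100 by 1.27, or 0.32 without a single low female spot. The median was 0.29, above 99.8% of random lists, with 11 of 12 names above 0; many of these are near-identical targets, and reduced to 5 distinct targets the median was 0.14 (percentile 92.2), within the central 95%. dre-miR-10c and ccr-miR-10d each have a brighter near-identical relative on the chip. The let-7 list, miRNAs that rise with differentiation in many animals, had 4 male-higher probes of 20 detected: dre-let-7g (1.60), ola-let-7g (1.38), dre-let-7c (1.29) and dre-let-7h (1.17). Its median was 0.09, within the central 95% of random lists, and dre-let-7c differed by 0.74 without a single low female spot. The list's median turned to -0.37 (6 names, percentile 9.6) with near-identical targets reduced. With 75th percentile scaling it was -0.16 and -0.12, and in the other settings it stayed above 0.

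Other male-higher probes were dre-miR-101b (8.73 ± 0.09 and 10.25 ± 0.08), dre-miR-365 (7.85 ± 0.07 and 9.20 ± 0.23), ola-miR-193a (9.43 ± 0.13 and 10.74 ± 0.13), and the custom probe novel_11 (11.16 ± 0.07 and 12.47 ± 0.11). dre-miR-457b of the miR-15 and miR-16 list (1.23) and ola-miR-130c of the miR-130 and miR-301 list (1.13) were the members of their lists that passed, and the medians of these lists, 0.19 and 0.11, lay within the central 95%. dre-miR-223, a miRNA of myeloid cells, differed by 1.30, or 0.79 without a single low female spot. The miR-122 probes of hepatocytes, ccr-miR-122 and dre-miR-122, were 2.5-fold and 2.40-fold higher in the male gonad at low intensity. Background subtracted and before normalization they read 239 and 228 in the male against 23.4 and 22.5 in the female, 10.2-fold for both. The authors' table gives 8.52-fold and 8.49-fold. Their list, 1 name placed among 40 neighbours, was within the central 95% of random draws.

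The kidney and gut list held 4 of the 8 female-higher probes. ccr-miR-194 read 10.39 ± 0.05 in the female and 9.09 ± 0.14 in the male gonad, dre-miR-194a 11.00 ± 0.07 and 9.70 ± 0.14, ola-miR-192-5p 10.48 ± 0.19 and 9.29 ± 0.40, and dre-miR-192 10.42 ± 0.14 and 9.40 ± 0.17. The list's median of -1.11 lay below all 10000 random lists, and all 6 names, variants of miR-192 and miR-194 that are not independent, were below 0. The other names, ola-miR-194-5p (-0.71) and dre-miR-194b (-0.11), did not pass. Reduced to 2 distinct targets the median was -1.16 (percentile 0.355). Without normalization these 4 probes stayed below 0 (median -0.68), and none differed by 1. The custom probe novel_6 (UGAUAGAACUCCGUGCCACAGGC) was 2.44-fold higher in the female gonad, 11.26 ± 0.02 against 9.97 ± 0.09. ola-miR-7, a miRNA of neuroendocrine cells, differed by -1.05, or by -0.81 without 1 low male spot, which is no longer past the rule. ola-miR-181a-5p differed by -1.11, or by -0.28 without 1 low male spot, likewise not past it. The remaining female-higher probe, dre-miR-458 (-1.12), was too dim for the rule on named probes and is named here after its value was seen.

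**Figure D2:**
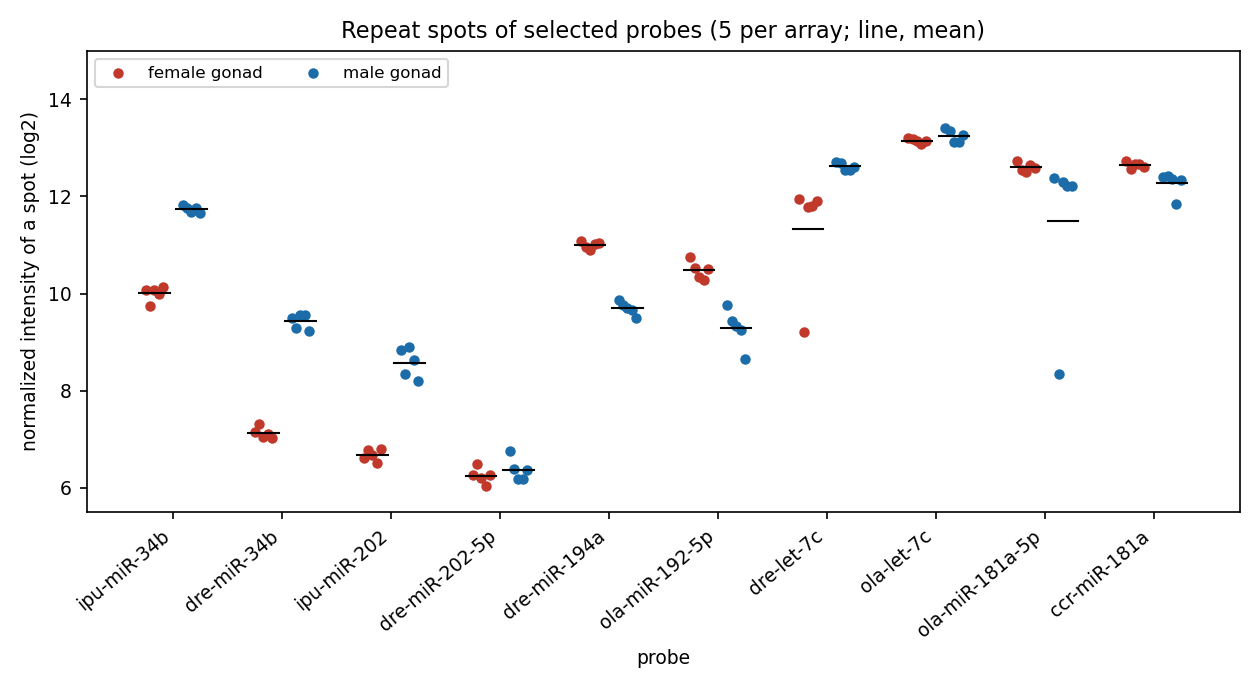
Normalized log2 intensity of the 5 repeat spots per array for 10 probes, female gonad in red and male gonad in blue, with the mean as a line; probes were picked after their values were seen. The spots of ipu-miR-34b and dre-miR-194a are tight and apart, dre-miR-202-5p is at the floor beside ipu-miR-202, and single low spots pull the means of dre-let-7c (female) and ola-miR-181a-5p (male).

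Of 29 lists, 3 lay beyond the central 95% of random lists toward the male and 3 toward the female. If members were independent, 1.45 lists would lie outside by chance. Members are often near-identical, so chance can put more lists outside. The miR-182, miR-183 and miR-96 list, a cluster known from sensory cells, had a median of -0.62 (percentile 0.135 of random lists) with 7 of 7 names below 0, yet none of its 12 detected probes passed the rule. Its brightest, hhi-miR-96, differed by -0.47. The endothelial miR-126 list had a median of -0.46 (percentile 1.34) with 3 of 4 names below 0, which are almost the same sequence, and ccr-miR-126-3p at -0.55. The fourth name, dre-miR-126b-3p, lay at 0.93, the other way, and ola-miR-126-3p, a dimmer probe of a counted name, at 0.17. Many lists hold such near-identical targets, which random lists do not share. With these reduced to the brightest probe on the whole chip, the miR-34, miR-202 and kidney and gut lists stayed beyond the central 95%, while the miR-10 list, the miR-182 list (-0.47, percentile 5.41) and the miR-126 list (1 name, -0.55, percentile 2.56) did not.

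**Figure D3:**
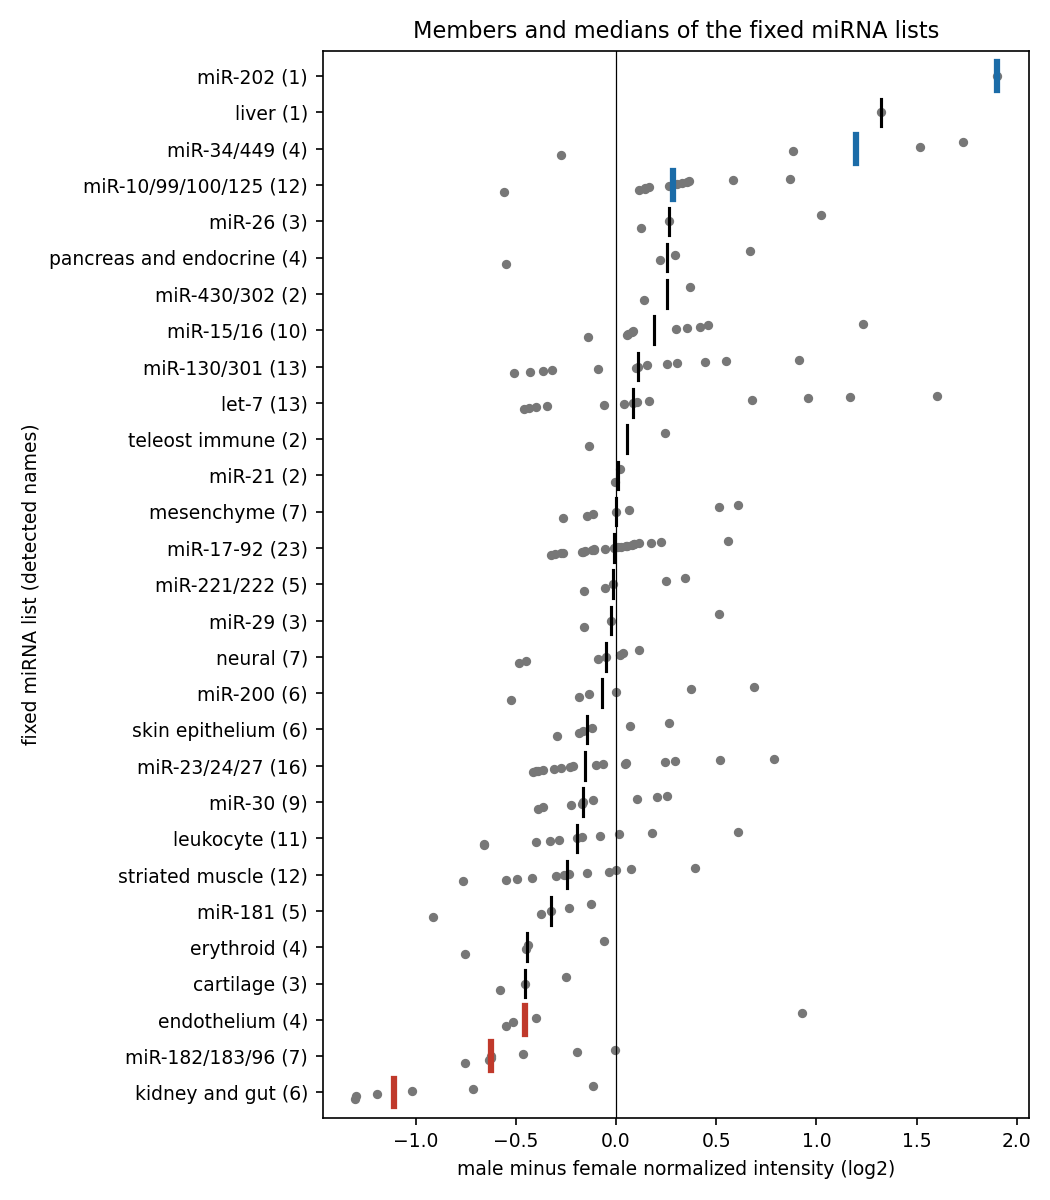
Difference between male and female normalized log2 intensity (x axis) for detected members of 29 fixed lists (y axis, number of names in parentheses), each point 1 miRNA name and the bar the median. Blue bars (the miR-202, miR-34 and miR-10 lists) lay above and red bars (endothelium, the miR-183 cluster, kidney and gut) below the central 95% of brightness-matched random lists.

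The other lists lay within the central 95% and held no probe past the rule except as given above. Among blood and immune markers, the erythroid list had a median of -0.44 with dre-miR-451 at -0.45, the leukocyte list -0.19, and the interferon-linked miR-462 and miR-731 list 0.06 with dre-miR-462 at -0.13. Among other tissue markers the medians were 0.00 for mesenchyme, -0.25 for striated muscle, -0.05 for neural (ola-miR-128 at 0.11), 0.26 for pancreas and endocrine (ipu-miR-375 at -0.55), -0.14 for skin epithelium (ipu-miR-205 at -0.19) and -0.45 for cartilage (dre-miR-140-3p at -0.45). Among families, the proliferation-linked miR-17-92 list had a median of -0.01 over 32 detected probes (dre-miR-19d at -0.27), and the miR-200 family of epithelial cells -0.07 over 12 (dre-miR-141 at -0.14). The medians were -0.33 for miR-181, 0.26 for miR-26 (hhi-miR-26 at 0.26), -0.16 for miR-23, miR-24 and miR-27 (ola-miR-24b-3p at 0.25), -0.16 for miR-30 (ipu-miR-30c at 0.21) and -0.03 for miR-29 (dre-miR-29b at -0.16). They were -0.02 for miR-221 and miR-222 (dre-miR-222a at 0.34), 0.01 for miR-21 and 0.26 for miR-430 and miR-302, a family of early embryos (hhi-miR-430b at 0.14).

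Probes for almost the same miRNA allowed a check on the chip itself, chosen after the data were seen. In 188 pairs of detected probes 1 target held the other whole and was at most 2 bases longer; their differences correlated across pairs with r = 0.60 (rho = 0.593, pairs that share probes and are not independent), with a median gap of 0.15 and an SD of 0.44 on the log2 scale. In 13 of these pairs at least one probe passed the rule, and in 3 both did, in the same direction: dre-let-7g with ola-let-7g, ccr-miR-122 with dre-miR-122 and ccr-miR-194 with dre-miR-194a. Against that, ola-miR-194-5p, also a near-twin of dre-miR-194a, did not pass, dre-miR-10c differed by 2.05 and ccr-miR-10c by 0.59, and dre-miR-223 by 1.30 and ola-miR-223 by -0.19. Of the 31 probes past the rule, 8 had a spot over 0.5 from the median of its probe, and 6 lost the call without such spots, novel_4 among them.

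The chip's control probes differed between the arrays by kind. Before normalization, control probes with M in their names were brighter on the male array by a median factor of 2.03, those with P in their names had 0.860 and miRNA probes 1.44. Among male-higher probes, dre-let-7g, ola-let-7g, dre-let-7h, dre-miR-10c, ccr-miR-10d, dre-miR-101b and ola-miR-130c had a target 1 or 2 mismatches from that of a probe at least 1 brighter on the log2 scale on the male array, and none of the 8 female-higher probes had. Of the 467 detected probes that were not male-higher, 57 (12.2%) had such a brighter relative. At any margin of brightness, 10 of the 23 male-higher and 1 of the 8 female-higher probes had such a relative.

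**Figure D4:**
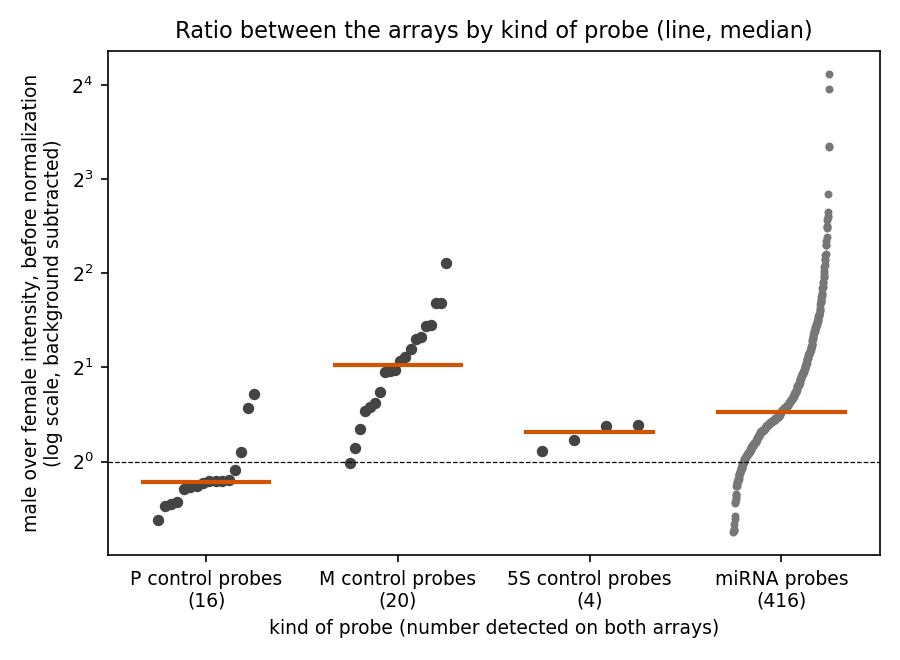
Male over female intensity before normalization, background subtracted and on a log scale (y axis), for P, M and 5S control probes and miRNA probes detected on both arrays (x axis), each point 1 probe and the line the median. M probes have a median of 2.03, P probes 0.860, 5S probes 1.24 and miRNA probes 1.44.

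The authors' deposited table comes from the same arrays, so it bears on the processing only and is not independent. All 31 probes past the rule had the same sign in it. Its differences correlated with those here across the 416 probes detected on both arrays (r = 0.928, rho = 0.910). With the same size limit on that table, 22 probes were higher in the male and 7 in the female gonad, of which 18 and 6 were among the 23 and 8.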

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

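The tests of the general gain for miR-34b, of an RNA with no probe, of relatives that are not brighter and of the normalization for miR-192 and miR-194, and the use of probes of almost the same target as a yardstick, were chosen only after the results were seen. Control probes, which the comparison of the sexes does not use, carried a signal of their own. Control probes with M in their names were brighter on the male array by a median factor of 2.03 before normalization (0.992 to 4.30, 19 of 20 above 1), while those with P in their names had 0.860 (0.649 to 1.64, 13 of 16 below 1) and 5S probes 1.24. In the numbered control sets, M over P was 2.66-fold higher on the male array, above 1 in 16 of 16. The control sequences are not given in the sources used here, and reading P and M as perfect match and mismatch rests on the names alone.

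Pattern 1 is the excess of male-higher probes, 23 against 8, which shrinks to 38 against 33 with plain background subtraction. If M marks mismatched probes, a candidate explanation is looser hybridisation on the male chip. A probe would then also read a relative at 1 or 2 mismatches. For 64 detected probes such a relative was at least 1 brighter on the log2 scale on the male array. They exceeded it in male minus female difference by a median of 0.43, at percentile 100 of brightness-matched unrelated pairs (their central 95% was -0.22 to 0.17). Many of the 64 share a relative, such as hhi-miR-196, or are near-identical to each other. The unrelated pairs are not, so the percentile overstates how rare this excess is. The share of male-higher probes with a relative at least 1 brighter was 0.304 (7 of 23), against 57 of 467 other detected probes (12.2%). Such relatives were thus more common among male-higher probes. Yet 11 of the 23, with miR-34b and miR-122 counted by 2 probes each, had no detected relative of any brightness at 1 or 2 mismatches. This argues against a relative at that distance as the source of the whole set. Relatives further off were not counted, such as dre-let-7a, 3 mismatches from novel_11 and brighter on the male array (13.33 against 12.47). Likewise dre-miR-16b was not counted for dre-miR-457b, though brighter on the male array (13.11 against 9.76). Yet dre-miR-16b lies 2 mismatches from ccr-miR-457b, whose target is that of dre-miR-457b without its first base. For the 5 male-higher probes whose relative was not brighter by 1 (median gap 0.018), that relative as the source stays open. Probes of almost the same target differed in level by up to 3.38 on the male array. But 3 of the 5 (dre-let-7c, novel_4 and ola-miR-100), and dre-miR-223 of those below, pass the rule only with a single low female spot. Of male-higher probes detected on both arrays, 15 had no relative brighter by 1, and a sturgeon RNA with no probe stays open for 13 of these. Their male over female ratio did not exceed the highest of M controls and probes with a brighter relative (7.16) by more than the spot SD. That bound is dre-let-7g, itself male-higher, so it takes the excess of a probe under test as mismatched signal. The highest M control alone (4.30) was exceeded by more than the spot SD by ipu-miR-34b (5.58), dre-miR-365 (5.95), dre-miR-457b (5.24) and both miR-122 probes (10.2). For these the answer depends on the bound. The 2 above the higher bound, dre-miR-34b and ipu-miR-202, were dim on the female array (49.1 and 26.6), which limits what their ratios exclude. Sex stays open as well, untested.

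Pattern 2 is miR-34b in the male gonad. Of other miR-34 and miR-449 probes the brightest, hhi-miR-449, lay at -1.81 on the log2 scale relative to ipu-miR-34b on the male array, past the spot SD set as the bound, and neither miR-34b probe had a detected relative at 1 or 2 mismatches (counted without gaps), both of which go against a brighter relative. It is left open because levels of different probes do not rank the RNAs: the level gap between probes of almost the same target had a median of 0.22 and an SD of 0.72, but 10 of 188 pairs had a gap at least as large, up to 3.38. The unnormalized ratio of ipu-miR-34b, 5.58 ± 0.66, lay above the highest M control (4.30) by more than its spot SD. It lay below the highest probe with a brighter relative (7.16), dre-let-7g, which is itself male-higher and under test. On that bound a gain of mismatched signal stays open for ipu-miR-34b. The targets of the miR-34b probes are the same sequence shifted by a single base, so their ratios are not separate lines of evidence. The ratio of dre-miR-34b, 15.6 ± 3.56, lay above both bounds and goes against such a gain, but over a female intensity of 49.1, near background. A difference between the sexes, untested with 1 fish each, cannot be told apart from these or from a difference between the fish or the chips.

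Pattern 3 is miR-192 and miR-194 in the female gonad. Normalization as the whole cause is argued against by the values without it, a median of -0.68 over the 4 probes (spot SD 0.19) against -1.30 to -1.02 with it. Normalization moved these probes by 0.54 to 0.60, a part of each difference, and without that move none reaches the size limit. Kidney or gut epithelium in the female dissection could give these miRNAs, and the miR-200 family of epithelial cells was at percentile 38.97 of matched lists. It was bright in both gonads, so a small share of such cells would be hidden, and tissue carried along cannot be told apart from a difference between the gonads.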

How the results depend on the processing

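Scaling to the P control probes, leaving out far spots and reducing near-identical targets, for counts and for lists, were chosen after seeing the data. No paired analysis was possible because each sex has 1 array. A set of 16 male-higher probes was kept in all 16 settings that change the background correction, scaling, averaging or source of values. Among them were ipu-miR-34b and dre-miR-34b, which have almost the same target. Of these 16 probes, 6 have a near-identical relative at least 1 brighter on the log2 scale on the male array. No normalization and scaling to P probes leave the male array brighter by a median of 0.45 and 0.66. A male-higher call could thus hardly be lost there, and a female-higher call hardly kept. The 14 settings that level the arrays kept the same 16 male-higher probes, and ccr-miR-194, dre-miR-194a, ola-miR-192-5p and novel_6 of the female-higher. Without such levelling no female-higher probe was kept. Signal over background limits probes near the empty spots: with their 99th percentile as the limit, 316 probes were detected on the female array. That limit was 238 on the female and 182 on the male array, further above the empty-spot median on the female array.

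Counts moved past 1.5 times as follows, male then female. No normalization gave 74 and 0, scaling to P probes 105 and 0, subtraction 38 and 33, a size limit of 2 gave 2 and 0, one of 0.58 gave 50 and 38, and near-identical targets reduced to the brightest gave 10 and 5. Only the female count moved with loess (4) and offset 16 (15). Leaving out far spots gave 20 and 6, and leaving out each repeat spot 21 to 26 and 8 to 11.

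The lists led by miR-34 and by the kidney and gut markers kept side and direction in every setting run, and the list led by miR-10 in all but the reduction of near-identical targets (0.14), where it dropped inside the central 95%. miR-202 dropped inside the central 95% with the authors' table (2.34, 1 name among 40 neighbours) and with undetected members (0.12). The list of miR-182, miR-183 and miR-96 did so with 75th percentile scaling over probes detected on both arrays (-0.52) or all probes (-0.47) and with near-identical targets reduced (-0.47), and its median turned to 0.085 without normalization and 0.30 with P scaling. The endothelial list did so with the authors' table (-0.34), without repeat spot 3 (-0.44) or 4 (-0.47) with the mean per name (-0.30) and with near-identical targets reduced (-0.55), and turned to 0.14 without normalization and 0.36 with P scaling. Those turns follow from the shift of the whole male array, which moves random lists too; in both settings the miR-182 list was at percentile 4.26 and the endothelial list at 2.05. The miR-15 and miR-16 list passed beyond the central 95% toward the male with 75th percentile scaling (0.18 and 0.23), no normalization (0.79), offset 16 (0.23), median spots (0.27), the authors' table (0.34), without repeat spot 2 (0.21) or 4 (0.24), and P scaling (1.004). miR-26 did so without repeat spot 4 (0.27) and miR-130 and miR-301 with the mean per name (0.18). Apart from calls that rest on a far spot, the cause was not tested.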

Other observations

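The groups below were looked at after the data were seen, and probes of 1 family are often near-identical, so their counts are not independent. Outside the fixed lists, 20 families had at least 3 detected probes. The miR-101 family had 7 of 7 probes above 0, with a median difference of 0.90 and 2 past the rule, dre-miR-101b (1.53) and ola-miR-101a-3p (1.01). Of the 7, 4 have a near-identical relative at least 1 brighter on the log2 scale on the male array. All 4 detected miR-135 probes lay between 0.48 and 0.62 toward the male and none passed; 3 of them have almost the same target and a brighter relative in the fourth, ola-miR-135b. Toward the female, 4 of 4 miR-1788 probes lay between -0.88 and -0.56, and 3 of 3 miR-31 probes between -0.73 and -0.52, none past the rule, while the 3 miR-458 probes ranged from -1.12 to -0.14. miR-193 and miR-365, which share genomic clusters in vertebrates, had male-higher probes in ola-miR-193a (1.31) and dre-miR-365 (1.35), but dre-miR-193b differed by -0.63 and ipu-miR-365 by -0.02.

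Of the 48 custom probes, 33 were detected on the female and 21 on the male array. Of the 33, 2 were higher in the male, 1 was higher in the female and 30 were neither; 30 of 33 lay below 0, with a median of -0.22, and 12 of the 33 were detected on the female array only, which favours values below 0. Among the 21 detected on both arrays, 19 lay below 0, with a median of -0.35, against a central 95% of -0.23 to 0.23 for standard probes of like brightness drawn as if unrelated. Both male-higher custom probes resemble let-7: novel_4 (AGAGGUAGUUGGUUGUAUAGUU) lies 2 mismatches and novel_11 (AGAGGUAGCAGGUUGCAUAGUU) 3 mismatches from dre-let-7a, which differed by 0.09. novel_4 differed by 1.04, or 0.52 without 1 low female spot, and novel_11 by 1.32. The female-higher novel_6 had its nearest standard probe 8 mismatches away.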
